A study of Arabidopsis thaliana with 12 samples.

How the data were processed

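Gene expression was measured in whole Arabidopsis seedlings on 12 one-colour Affymetrix arrays of 22810 probe sets, with biotin-labelled cRNA and 1 array per sample. The groups were Col-0 and hai1-2 at -0.25 MPa and at -1.2 MPa, with 3 arrays each, and were taken from the sample labels. The deposited values are signal intensities on a linear scale, and per the submitters' processing notes they were made with MAS5, whose version, scaling target and filters are not given in the sources used here. On each array the mean intensity after leaving out 2% of probe sets at each end was the same, so the deposited values were used without further normalization. Medians of the log2 values differed by 0.116 between arrays at most. MAS5 values of weakly expressed genes are noisy, and between 3331 and 3929 probe sets per array had a signal below 16. The number of arrays limits the precision of every comparison. No 2 arrays held identical values.

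Signals were taken as log2(value + 16), a scale on which the change of weak genes is understated. The 64 Affymetrix control probe sets were left out, and of the others the lowest 25% by mean log2 over all arrays, 5687 probe sets with a mean below 5.67, were removed, which left 17059. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (version 1.17.8 of data.table for reading), and 5 contrasts were tested with variances moderated along an intensity trend: low water potential against control in each genotype, hai1-2 against Col-0 at each water potential, and the genotype by treatment interaction. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the probe sets tested, and called at an adjusted p under 0.05. SE is that of the moderated fit, and SD is that of the 3 signals of a group.

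Gene names came from an annotation of the platform, updated through TAIR10.1, which was used for names only. It gives 1 gene for 13513 probe sets, of which 13436 had a locus in the reference, several for 503 and none for 8730, and among those tested 1 for 9396, several for 355 and none for 7308. Probe sets without a gene in it are unnamed here and are given by their identifier. HAI1 is not among the genes it names. The named genes were the 10 largest rises and 10 largest falls per comparison among called single-gene probe sets whose groups did not overlap, up to 4 called members of each gene list by smallest adjusted p, up to 2 members that were not called by highest mean log2, and all members of the proline list. Other genes named were chosen after their values were seen, and this is stated where they are first given.

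Gene lists held 399 loci in 24 lists, of which 75 loci were measured by a single-gene probe set and 64 were tested. Lists with no measured locus included clade A PP2C phosphatases, PYR/PYL ABA receptors, SnRK2 kinases, ABA and drought transcription factors, and ABA synthesis and catabolism. These could not be examined by name, so their absence below is not a negative result. Lists with tested members were dehydrins and LEA proteins (16), expansins and XTHs (17), photosynthesis as a shoot marker (5), flavonoid and anthocyanin synthesis (4), auxin early response (4), root markers (3), cell division (3), other ABA and drought markers (2), proline (2), starch degradation (2), jasmonate (2), aliphatic glucosinolates (2), salicylic acid defence (1) and heat shock (1). The 5 lists with at least 4 tested members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with the same intensity trend, adjusted over the lists within a comparison. A run of camera without that trend had been seen first, and is given among the alternatives. camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. The comparisons, tests, lists, rule for named genes and alternatives were chosen before the data were examined, except where stated.

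Each of 3 independent experiments gave 1 sample to every group, per the series' design text, so the replicate number pairs samples. Deviations from the group means of arrays with the same number correlated between genotypes at 0.128 to 0.517 on control plates and 0.227 to 0.263 at -1.2 MPa, against -0.422 to 0.164 and -0.136 to -0.104 for different numbers. Between control and stressed plates of a genotype, same-numbered arrays correlated at -0.0232 to 0.0929 in Col-0 and -0.0199 to 0.0886 in hai1-2. The fit with the experiment as a block was an alternative. Other alternatives were pseudocounts of 1 and 64, no filter or removal of the lower 50% of probe sets, quantile normalization or median centring, variances without the trend or with robust moderation, array weights, 1 probe set per gene, only the 6 arrays compared, a 2-fold minimum, and leaving out each array. Pairing within each treatment was added after the data were seen. So was a least-squares fit of group means with the log2 ratio of 5' to 3' GAPDH signal as a covariate, to the mean of a list per array or to 1 probe set.

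The procedure was tested on simulated data for hai1-2 against Col-0 at -1.2 MPa, with 17059 probe sets of which 200 were changed, in 10 runs. It recovered 61.4% of those changed 2-fold and 94.2% of those changed 4-fold, with the right sign in 100% of calls and 4.02% false calls. A simulated list shift of 0.5 was called in 10 of 10 runs, and 0 of 40 other list tests were called. The simulated noise was independent between probe sets and between arrays, so these runs cannot show how the tests behave with correlated genes or paired arrays. The shares recovered also depend on the 200 planted changes, since the adjusted threshold is stricter where fewer probe sets change. The planted shift of 0.5, in dehydrins and LEA proteins, was larger than the 0.38 of that list in the real data at -1.2 MPa. In the real data the estimated inter-gene correlation was 0.0479 for dehydrins and LEA proteins and 0.0713 for expansins and XTHs.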

Results

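The series measured transcripts in whole Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutant hai1-2, which carries a lesion in HAI1 (At5g59220), a clade A type 2C protein phosphatase of the abscisic acid (ABA) signalling pathway. Seedlings 7 days old were moved to fresh plates at a water potential of -0.25 MPa, the control, or to plates infused with polyethylene glycol at -1.2 MPa, a low water potential that draws water from the plant as drying soil does, and were collected 96 h later. The 4 groups, 2 genotypes by 2 water potentials, held 3 arrays each, and each of 3 independent experiments gave 1 array to every group. On the 12 one-colour arrays, median signal lay between 195 and 212 over 22810 probe sets, and correlations between pairs of arrays lay between 0.915 and 0.982. The annotation used here pairs no probe set with HAI1, so its level could not be given by name and the genotype labels were not checked against it. The unnamed 247723_at, described below, may measure HAI1. The ratio of 5' to 3' actin signal, a sign of RNA integrity, was 0.268 on Col-0 control replicate 3 and 0.303 to 0.564 on the other 11 arrays. The same ratio for GAPDH was 1.00 ± 0.0192 in Col-0 and 0.943 ± 0.0894 in hai1-2 on control plates, and 0.869 ± 0.101 and 1.11 ± 0.0585 at -1.2 MPa (SD, n = 3). It lay between 0.756 and 0.952 on stressed Col-0 arrays and between 1.05 and 1.16 on stressed hai1-2 arrays, so these groups did not overlap. The ratio for ubiquitin did overlap there, at 0.779 to 0.980 in stressed Col-0 and 0.786 to 0.892 in stressed hai1-2. It differed by experiment instead, at 0.657 to 0.786 on the arrays of experiment 3 and 0.852 to 0.980 on those of experiments 1 and 2.

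The first comparison asked which transcripts the wild type changed after 96 h at low water potential. Transcripts of late embryogenesis abundant (LEA) proteins, which protect dehydrating cells, and of anthocyanin enzymes rose, and those of photosynthesis proteins fell, the last as a list not called with an estimated correlation (adjusted p = 0.0570, in a range of 4.3e-05 to 0.0570 over the alternatives). Among called single-gene probe sets whose groups did not overlap, to which the largest rises and falls below are limited, AT3G02480 rose by 7.27 ± 0.29 on the log2 scale (SE, 3 arrays per group), from a signal of 15.9 ± 15.0 (SD, n = 3) to 4695 ± 1173. SAG29, a sugar transporter of the SWEET family that is strongly expressed in senescing leaves, rose by 7.07 ± 0.24, from 21.0 ± 9.24 to 4992 ± 1285. Both control signals lie near the constant of 16 added before the log, so the size of these changes depends on it: with 1 and 64 added, they were 8.44 and 5.88 for AT3G02480 and 7.86 and 5.86 for SAG29, and with 64 added DFR (5.93) lay above both. The anthocyanin glucosyltransferase AT4G14090 rose by 6.68 ± 0.21 and DFR, the dihydroflavonol reductase that commits flux to anthocyanins, by 6.48 ± 0.28, from 98.4 ± 48.1 to 9592 ± 783.

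The other genes of the 10 largest rises were AT2G37870 at 6.25, the LEA gene AT3G17520 at 6.22, AT2G21820 at 6.03, LEA4-5 at 5.99, COR15A, which encodes a chloroplast cryoprotective protein, at 5.84 and AT4G33550 at 5.73. The adjusted p of these 10 genes ran from 3.3e-10 to 2.9e-07. Over all called probe sets, named or not, changes reached 8.59 and -6.10. The largest fall within the limits above was that of AT3G05730, -6.09 ± 0.51, from a signal of 7929.9 ± 1496 to 108 ± 59.9 (adjusted p = 9.5e-07). AT3G16670 changed by -6.07, the GASA family gene AT1G22690 by -5.17, the invertase or pectin methylesterase inhibitor gene AT5G62360 by -4.86 and TBL45, of a family that acetylates wall polysaccharides, by -4.61. Smaller falls were those of the GDSL lipase gene AT1G33811 (-4.20), the thionin gene AT1G66100 (-4.16), the calmodulin-like gene AT2G41090 (-4.15), the glutaredoxin gene AT3G62950 (-3.99) and AT1G66940 (-3.88). The size and order of these falls depend on the added constant as well: with 1 and 64 added, AT3G16670 stood at -6.44 and -5.30, AT3G05730 at -6.30 and -5.58, and AT5G62360 at -6.18 and -3.54, so that with 1 added AT3G16670 led, and AT3G62950 stood at -2.36 with 64 added.

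Of the 16 dehydrin and LEA genes tested, which encode hydrophilic proteins of desiccating cells, 15 rose and 1, COR47, did not pass the threshold at 0.47 ± 0.17 (adjusted p = 0.0513; it passed without any 1 of Col-0 control replicate 2, Col-0 stress replicate 1, hai1-2 control replicate 2 and hai1-2 stress replicate 2, at 0.57, 0.57, 0.47 and 0.47). COR47 also passed with the lower 50% of probe sets removed, quantile normalization and robust moderation (adjusted p = 0.0465, 0.0235 and 0.0490, in a range of 0.0235 to 0.224 over the alternatives). DI21 rose by 3.16, and the mean change of the list was 2.67 (camera adjusted p = 1.1e-10, and adjusted p = 0.00296 with an estimated correlation). Adjusted over the list alone, 16 of the 16 passed. The 4 flavonoid and anthocyanin genes tested all rose, by a mean of 5.76 (camera adjusted p = 4.6e-08, and adjusted p = 0.00998 with an estimated correlation). They were DFR, the glycosyltransferases AT4G14090 and UF3GT (5.48), and the anthocyanin malonyltransferase AT5MAT (4.38). Over this comparison the GAPDH ratio went from 1.00 to 0.869. Both tested genes of the other ABA and drought markers rose, the aldehyde dehydrogenase ALDH7B4 by 1.96 ± 0.14 and AT4G25580 by 1.74 ± 0.38.

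All 5 photosynthesis genes tested fell, among them the photosystem I subunit PSAN at -1.38 ± 0.15 and the light-harvesting proteins LHCB4.3 (-1.15 ± 0.17) and LHCB4.2 (-0.65 ± 0.17). A further member, LHCB4.1, did not pass without Col-0 control replicates 1 or 2 or Col-0 stress replicate 2 (-0.40, -0.42 and -0.46) or with quantile normalization (-0.33, adjusted p = 0.0706, in a range of 8.9e-04 to 0.0706). The list's mean change was -0.82 (camera adjusted p = 0.00113), and its call was lost with an estimated correlation (adjusted p = 0.0570, the highest of a range of 4.3e-05 to 0.0570 over the alternatives). Beside that fall, of 3 root markers, the root-hair expansins EXPA7 and EXPA18 rose by 2.34 and 1.41, and the root beta-glucosidase PYK10 stood at 0.18 ± 0.13 without passing (adjusted p = 0.333), but passed with quantile normalization (0.40, adjusted p = 0.0363, in a range of 0.0363 to 0.845). Expansins, proteins that loosen the cell wall, and xyloglucan endotransglucosylases (XTHs), wall enzymes listed with them, went both ways. Of 17 tested, 6 rose, 5 fell and 6 did not pass, with EXPA9 at 1.68, XTH19 at 1.63, XTH20 at 1.299 and XTH16 at -3.005. That list's mean was -0.13, its median 0.19 and its test pointed upwards without a call (camera adjusted p = 0.912), and downwards without Col-0 control replicate 1 or hai1-2 control replicate 2 (adjusted p = 0.805 and 0.965, in a range of 0.264 to 0.997 over the alternatives).

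Of the 4 auxin early-response genes tested, IAA30 (-0.81) and the auxin-conjugating enzyme gene WES1 (-0.98) fell, while GH3.3, another such enzyme gene, at -1.28 ± 0.52 and IAA29 at -1.71 ± 0.71 did not pass. The list's mean change was -1.19 (camera adjusted p = 0.0415), its call was lost with an estimated correlation (adjusted p = 0.261), and over the alternatives its adjusted p ran from 0.00866 to 0.261. The list's call also ended without Col-0 control replicates 2 or 3 (0.0669 and 0.0873) or Col-0 stress replicates 1 or 2 (0.0557 and 0.0568). GH3.3 passed without Col-0 control replicate 1 or hai1-2 control replicate 1 (-2.01 and -1.28) and with the experiment as a block (adjusted p = 0.0411, in a range of 0.00121 to 0.243). IAA29 passed without Col-0 control replicate 1 or hai1-2 control replicate 3 (-2.13 and -1.71) and with the 6 arrays alone (adjusted p = 0.0444, in a range of 0.0308 to 0.327). IAA30 did not pass without Col-0 control replicate 3 or Col-0 stress replicate 2 (-0.64 and -0.69), nor WES1 without Col-0 control replicate 2 or Col-0 stress replicates 1 or 3 (-0.51, -0.88 and -0.99) or with the 6 arrays alone (adjusted p = 0.0564, in a range of 0.00795 to 0.0914). Adjusted over the list alone, all 4 passed.

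Lists of fewer than 4 genes were described but not tested. In these, the jasmonate-inducible thionin THI2.1 rose by 4.99 ± 0.32 and the small heat shock protein ATHSP22.0 by 3.48 ± 0.33. The proline-related DELTA-OAT, an ornithine aminotransferase, rose by 0.75 ± 0.12 and the proline dehydrogenase AT5G38710 stood at -0.43 ± 0.28 (adjusted p = 0.260, and past the threshold without Col-0 control replicate 1, at -0.76), while the alpha-amylase AMY1 rose by 1.77 ± 0.29. The cell division genes AUR1, an Aurora kinase, and PRL, a replication licensing factor, stood at -0.37 ± 0.15 and -0.42 ± 0.17 without passing, and so did the glucosinolate gene BCAT4 at -0.45 ± 0.24 and the jasmonate-responsive defensin PDF1.2 at -1.06 ± 0.45. Without Col-0 control replicate 1, AUR1 and PDF1.2 passed, at -0.47 and -1.60. AUR1 also passed with quantile normalization and median centring (adjusted p = 0.0487 and 0.0411, in a range of 0.0384 to 0.245), and PRL with these and with the experiment as a block (adjusted p = 0.0423, 0.0459 and 0.0355, in a range of 0.0355 to 0.258). SAG101, of salicylic acid defence, stood at -0.26 ± 0.26, and at 0.03 without Col-0 control replicate 3. In all, 3083 probe sets rose and 2755 fell of 17059 tested with limma, 1234 and 1258 of them by at least 2-fold, and 7430 had an unadjusted p under 0.05 against 853 by chance.

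The second comparison put the same question to hai1-2. Over all called probe sets, changes reached 8.27 and -5.44. AT3G02480 rose by 6.76 ± 0.29, from 54.5 ± 13.3 to 7683 ± 1753, SAG29 by 6.71 ± 0.24, AT3G17520 by 6.62 ± 0.45, AT4G14090 by 6.44 ± 0.21 and UF3GT by 6.20 ± 0.28. The thionin THI2.1 rose by 5.89 ± 0.32, from 43.8 ± 15.1 to 3475 ± 349. The other genes of the 10 largest rises were AT2G21820 (6.45), LEA4-5 (6.18), AT1G16850 (6.16) and DFR (5.93). Within the limits given for Col-0, the largest falls were those of AT3G05730 (-5.16 ± 0.51), AT2G41090 (-4.80 ± 0.26) and AT2G10940 (-4.65 ± 0.34). They were followed by AT3G16670 (-4.52), AT1G22690 (-4.49), AT1G33811 (-4.43), AT1G66100 (-4.35), TBL45 (-4.33), AT3G04210 (-4.30) and AT1G06830 (-4.27). These orders depend on the added constant too. With 1 added, AT3G17520 (7.36), AT2G21820 (7.26) and SAG29 (7.17) rose more than AT3G02480 (7.12), which led with 64 added (6.01), and AT1G06830 and AT3G04210 stood at -5.32 and -5.27 with 1 and at -3.12 and -3.07 with 64 added.

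In hai1-2, 14 of the 16 dehydrin and LEA genes rose, 15 when adjusted over the list alone, with COR15A at 5.88 and DI21 at 3.69, and COR47 did not pass at 0.43 ± 0.17 (adjusted p = 0.0680; it passed without Col-0 stress replicate 3, hai1-2 control replicate 2 or hai1-2 stress replicate 2, at 0.43, 0.54 and 0.54). It also passed with quantile normalization, array weights and the 6 arrays alone (adjusted p = 0.0250, 0.0265 and 0.0484, in a range of 0.0250 to 0.191). The other member that did not pass was COR15B, at 0.04 (adjusted p = 0.953). The list's mean was 2.74 (camera adjusted p = 1.7e-09, and adjusted p = 0.00443 with an estimated correlation). All 4 anthocyanin genes rose, by a mean of 5.75 (camera adjusted p = 1.8e-07, and adjusted p = 0.0126 with an estimated correlation), AT5MAT by 4.43. All 5 photosynthesis genes fell, by a mean of -0.99 (camera adjusted p = 2.6e-04, and adjusted p = 0.0365 with an estimated correlation), with PSAN at -1.44 and LHCB4.3 at -1.21. Beside that fall, the 3 root markers rose, EXPA7 by 1.85, EXPA18 by 1.24 and PYK10 by 0.40. EXPA18 did not pass without hai1-2 control replicate 1 or hai1-2 stress replicate 1 (0.90 and 1.05), nor PYK10 without hai1-2 control replicates 1 or 3 or any 1 stressed hai1-2 array (0.33 to 0.43). PYK10 did not pass with no filter, median centring or no trend either (adjusted p = 0.0745, 0.0742 and 0.0585, in a range of 0.00504 to 0.115). The 3 cell division genes fell, with PRL at -0.85 ± 0.17 and AUR1 at -0.61 ± 0.15, as did both tested glucosinolate genes, with BCAT4 at -1.18 ± 0.24. The third cell division gene, AUR2 (-0.47), did not pass without Col-0 stress replicate 1, hai1-2 control replicates 1 or 2 or any 1 stressed hai1-2 array (-0.32 to -0.54), nor with no filter or the 6 arrays alone (adjusted p = 0.0623 and 0.0532, in a range of 0.0233 to 0.175). The other glucosinolate gene, AT2G31790, did not pass without hai1-2 control replicate 1 or hai1-2 stress replicates 1 or 2 (-0.54, -0.77 and -0.73). Over this comparison the GAPDH ratio went from 0.943 to 1.11.

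Of the 17 expansins and XTHs, 3 rose in hai1-2 (4 when adjusted over the list alone) and 7 fell, with EXPA9 at 1.33, EXPA8 at -2.29, EXLA2 at -1.98 and XTH16 at -3.15. The list was not called (mean -0.56, camera adjusted p = 0.149). Nor was auxin early response, of which 1 member fell, WES1 at -1.05 (mean -1.04, camera adjusted p = 0.0870). That list passed without hai1-2 control replicate 1 (adjusted p = 0.0398), with a range of 0.0292 to 0.319 over the alternatives, and WES1 did not pass without hai1-2 control replicates 2 or 3 or hai1-2 stress replicate 3 (-0.96, -0.91 and -0.95). DELTA-OAT rose by 1.25 ± 0.12 and AT5G38710 fell, at -0.85 ± 0.28 (adjusted p = 0.0264), though not without hai1-2 control replicate 3 or hai1-2 stress replicates 1 or 3 (-0.70, -0.82 and -0.78). AMY1 rose by 2.64 ± 0.29, the starch-degrading DPE1 by 0.76 ± 0.17, ALDH7B4 by 2.31 ± 0.14, AT4G25580 by 1.17 ± 0.38 and ATHSP22.0 by 3.35 ± 0.33. AT4G25580 did not pass without hai1-2 control replicates 1 or 2 or hai1-2 stress replicates 1 or 3 (1.15, 0.84, 1.04 and 1.18). PDF1.2 at -0.93 ± 0.45 and SAG101 at -0.51 ± 0.26 did not pass, though PDF1.2 did without Col-0 control replicates 1 or 3 (adjusted p = 0.0495 and 0.0464) and with array weights or the 6 arrays alone (adjusted p = 0.0288 and 0.0461, in a range of 0.0288 to 0.376 over the alternatives). In all, 3390 probe sets rose and 3031 fell, 1265 and 1436 of them by at least 2-fold, and 7940 had an unadjusted p under 0.05 against 853 by chance.

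The 2 responses shared most of their probe sets. Both genotypes raised 2337 probe sets, against 613 for independent lists, both lowered 2289, against 490 for independent lists, and 2 moved in opposite directions. Across the 17059 probe sets, which are not independent replicates, the responses correlated at r = 0.926 (Pearson) and 0.859 (Spearman). The 2 responses have no array in common, but each experiment gave arrays to both, and within single experiments r lay between 0.774 and 0.878.

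**Figure D1:**
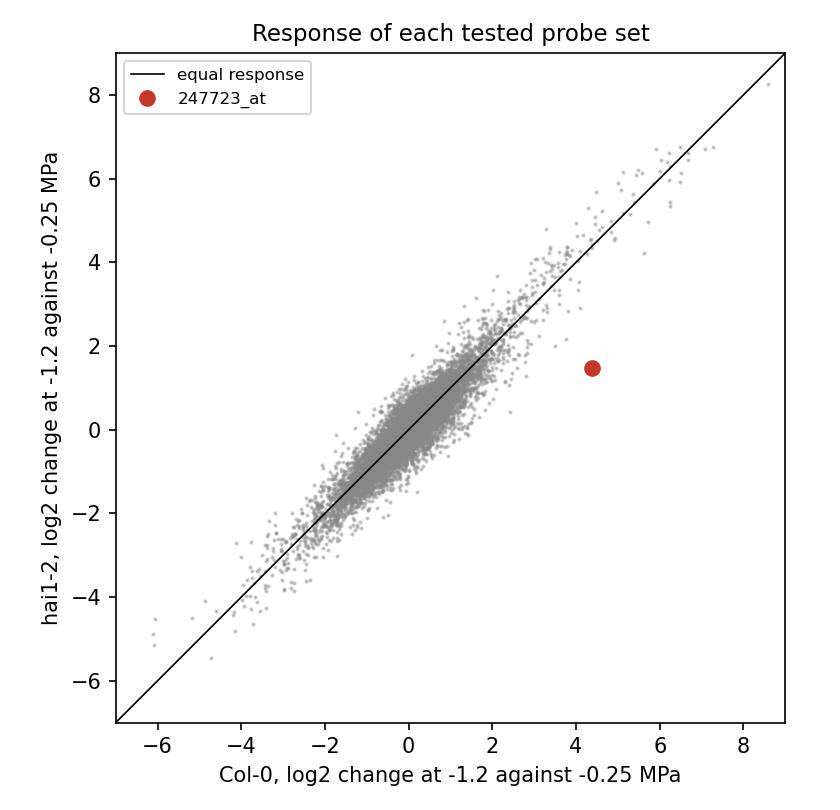
Log2 change at -1.2 against -0.25 MPa in Col-0 (x axis) and hai1-2 (y axis) for each of 17059 probe sets, each point 1 probe set and the line an equal response. Probe set 247723_at, in red, lies off the line at 4.38 in Col-0 and 1.47 in hai1-2.

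On control plates the question was whether the mutant differed from the wild type before stress, and no probe set passed. The list of dehydrin and LEA genes lay higher in hai1-2, at a mean log2 difference of 0.31 with 13 of 16 genes positive, in 3 of 3 experiments (0.18, 0.61 and 0.14). Its camera adjusted p was 4.9e-04, which did not hold with an estimated correlation (adjusted p = 0.0641) or without hai1-2 control replicate 2 (adjusted p = 0.0603), and ran from 7.6e-05 to 0.170 over the alternatives. The expansin and XTH list also lay higher, by a mean of 0.20 with 12 of 17 positive (camera adjusted p = 0.00925), and lost its call with an estimated correlation (adjusted p = 0.163). Without hai1-2 control replicate 2, Col-0 control replicate 1 or Col-0 control replicate 3, its adjusted p was 0.314, 0.159 and 0.0933, in a range of 0.00108 to 0.404 over the alternatives. Beside this list, the 3 root markers had a mean of 0.17, with -0.08, 0.08 and 0.49 in experiments 1, 2 and 3, and the GAPDH ratio was 1.00 in Col-0 and 0.943 in hai1-2. No single member of the LEA or the expansin and XTH list passed, over all genes or adjusted over the list alone. The flavonoid, photosynthesis and auxin lists were not called (means 0.06, 0.12 and -0.11, camera adjusted p = 0.535, 0.0900 and 0.792), and without hai1-2 control replicate 3 the photosynthesis list gave an adjusted p of 0.0247, in a range of 0.0247 to 0.603. Adjusted over the list alone, 1 flavonoid gene lay higher in hai1-2 and 1 lower, and 1 of the 2 other ABA and drought markers lay higher.

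QQS, a gene linked to leaf starch content that was chosen after its values were seen, had a signal of 1744 ± 693 in Col-0 and 549 ± 13.9 in hai1-2, a log2 difference of -1.57 ± 0.24 that did not pass (limma adjusted p = 0.269). With the experiment as a block, QQS was the 1 probe set that passed, at adjusted p = 0.0258, and it passed without Col-0 control replicate 2 (adjusted p = 0.0249), in a range of 0.0195 to 0.999 over the alternatives. Paired within each treatment, a fit added after the data were seen, QQS (adjusted p = 0.0195) and AT2G19970, higher in hai1-2 (adjusted p = 0.0229, in a range of 0.0229 to 1.000), passed. The proline gene DELTA-OAT stood at -0.07 ± 0.12 and AMY1 at 0.37 ± 0.29. limma thus called 0 of 17059 probe sets, with 546 at an unadjusted p under 0.05 against 853 by chance. This fit did not take out the experiment, although same-numbered control arrays of the 2 genotypes correlated at 0.128 to 0.517. Its spread therefore held differences between experiments, which makes the test cautious. With the experiment as a block, 658 had an unadjusted p under 0.05. Simulated data were made for the comparison at -1.2 MPa, with 200 changed probe sets and noise independent between probe sets and arrays. In these, 61.4% of probe sets changed 2-fold were recovered. Of those changed 4-fold, 94.2% were. The adjusted threshold is stricter where fewer probe sets change, so these shares are not the power of the comparison on control plates.

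At -1.2 MPa the comparison of hai1-2 with Col-0 gave 1 called probe set, 247723_at, which the annotation pairs with no gene. Its signal was 2967 ± 316 in stressed Col-0 and 326 ± 61.8 in stressed hai1-2, a log2 difference of -3.13 ± 0.19 (adjusted p = 4.2e-06, lower in 3 of 3 experiments). On control plates the signals were 129.6 ± 34.8 and 106 ± 7.75. Dehydrin and LEA genes again lay higher in hai1-2, by a mean of 0.38 with 12 of 16 positive, in 3 of 3 experiments (0.49, 0.41 and 0.24). The camera adjusted p was 5.7e-05, and the call held with an estimated correlation (adjusted p = 0.0354, in a range of 3.0e-07 to 0.0478 over the alternatives). The GAPDH ratio differed along with the list, at 0.869 ± 0.101 in stressed Col-0 and 1.11 ± 0.0585 in stressed hai1-2, higher in 3 of 3 experiments. The actin ratio overlapped between these groups, at 0.406 ± 0.139 and 0.456 ± 0.0631, and so did the ubiquitin ratio. Members chosen after their values were seen were LEA18 at 1.23 ± 0.35 and the dehydrin LTI30 at 0.80 ± 0.25, neither past the threshold on its own (adjusted p = 0.705 and 0.743). The members that lay lower, also without passing, were COR15B (-0.21), AT4G38410 (-0.12), AT2G46140 (-0.09) and AT2G44060 (-0.03).

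The expansin and XTH list lay lower in stressed hai1-2, by a mean of -0.24 with 12 of 17 negative, among them EXPA4 at -0.53 ± 0.23. Its call was marginal (camera adjusted p = 0.0477) and was lost with an estimated correlation (adjusted p = 0.306), in a range of 0.00719 to 0.372 over the alternatives. Leaving out Col-0 control replicate 2, Col-0 stress replicates 1 or 3, hai1-2 control replicate 3 or hai1-2 stress replicates 1 or 3 also ended it, at 0.0690, 0.104, 0.134, 0.0509, 0.0567 and 0.353. The flavonoid, photosynthesis and auxin lists were not called (means 0.05, -0.05 and 0.04, each with camera adjusted p = 0.617). Beside this list, the GAPDH ratio was 0.869 in stressed Col-0 and 1.11 in stressed hai1-2, and the 3 root markers had a mean of 0.02 and a median of -0.01.

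Among genes that did not pass, AMY1 had a signal of 153 ± 41.5 in stressed Col-0 and 396 ± 149 in stressed hai1-2 (1.24 ± 0.29, adjusted p = 0.584). THI2.1 differed by 1.21 ± 0.32, DELTA-OAT by 0.43 ± 0.12 and AT5G38710 by -0.41 ± 0.28, with adjusted p = 0.598, 0.670 and 0.993. Adjusted over each list alone, 1 of the 2 tested genes passed as higher in each of the starch degradation, jasmonate and proline lists. QQS, at 1061 ± 122 and 366 ± 87.1, differed by -1.52 ± 0.24 (adjusted p = 0.126). With the experiment as a block, 3 probe sets passed, all lower in hai1-2: 247723_at, QQS (adjusted p = 0.0182) and the unnamed 258675_at (-1.03, adjusted p = 0.0493). QQS also passed without Col-0 control replicates 2 or 3 (adjusted p = 0.0304 and 0.0198) and with array weights or the 6 arrays alone (adjusted p = 0.0109 and 0.0427), in a range of 0.0109 to 0.788. Chosen after their values were seen, 264886_at passed without hai1-2 stress replicate 2 (-3.46, adjusted p = 0.0278) and AT5G63180 without hai1-2 stress replicate 3 (-1.29, adjusted p = 0.0252) and with array weights (adjusted p = 0.0229, in a range of 0.0229 to 0.664). Paired within each treatment, a fit added after the data were seen, 2 probe sets passed as higher and 9 as lower. AMY1 then passed (adjusted p = 0.0370, in a range of 0.0370 to 1.000 over the alternatives), as did QQS (0.0127), AT5G63180 (0.0364) and the endoglucanase gene GH9B8 (0.0370, in a range of 0.0370 to 1.000). Without pairing, limma thus called 0 higher and 1 lower of 17059, with 953 at an unadjusted p under 0.05 against 853 by chance.

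**Figure D2:**
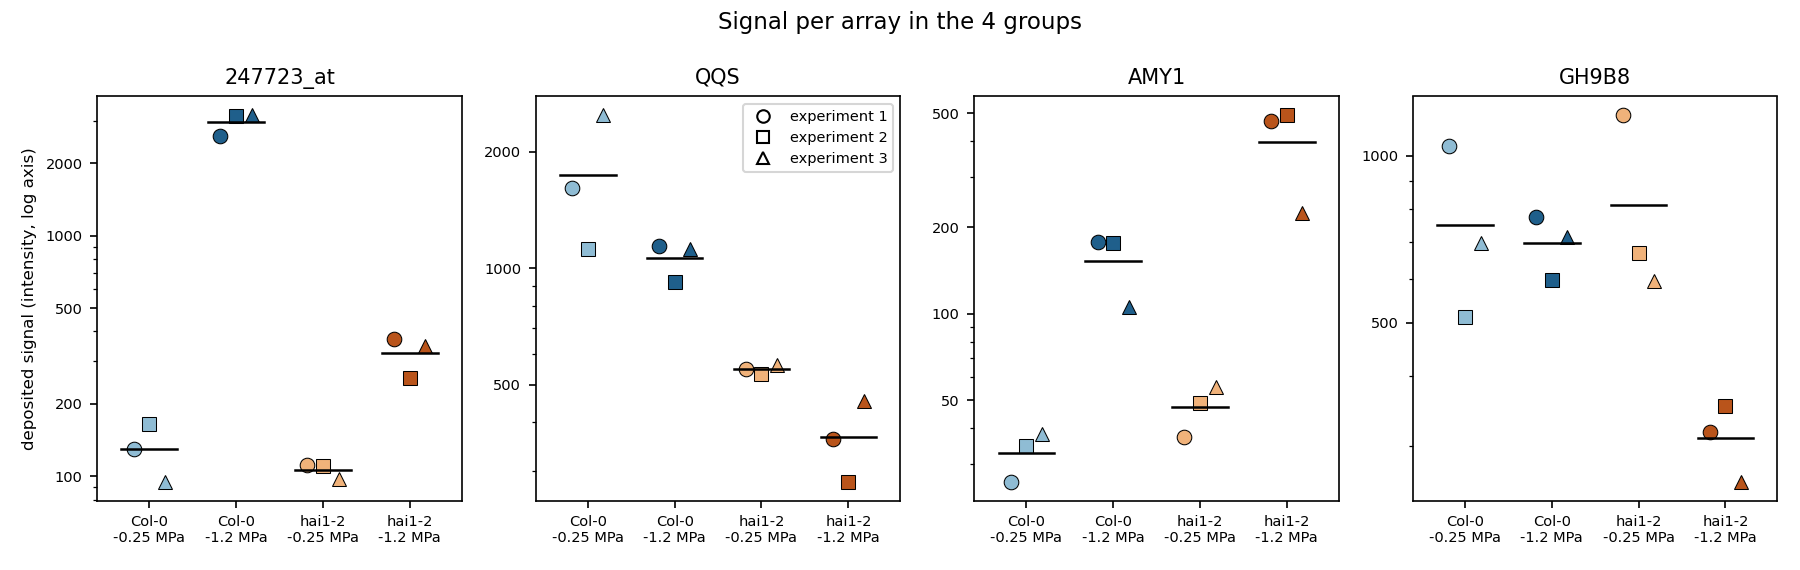
Deposited signal on a log axis for probe set 247723_at and the genes QQS, AMY1 and GH9B8 in the 4 groups, each point 1 array with its experiment as the symbol and the line the group mean. For 247723_at, stressed Col-0 arrays lie between 2603 and 3174 and stressed hai1-2 arrays between 256 and 373.

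Whether the response itself differed between genotypes was tested as an interaction, the hai1-2 response minus the Col-0 response. The unnamed 247723_at again gave the 1 call: it rose by 4.38 ± 0.19 in Col-0 and by 1.47 ± 0.19 in hai1-2, an interaction of -2.91 ± 0.27 (adjusted p = 9.0e-04). The expansin and XTH list responded lower in hai1-2, with a mean interaction of -0.43, 13 of 17 genes negative and all 3 experiments below 0 (-0.40, -0.26 and -0.64). Its camera adjusted p was 0.00225, and the call was lost with an estimated correlation (adjusted p = 0.162) and without hai1-2 control replicate 2 (adjusted p = 0.0854), in a range of 1.7e-04 to 0.329 over the alternatives. Beside it, the GAPDH ratio went from 1.00 to 0.869 in Col-0 and from 0.943 to 1.11 in hai1-2. EXPA4, for example, rose by 1.05 ± 0.23 in Col-0 and stood at 0.19 ± 0.23 in hai1-2 without passing there, and its own interaction of -0.86 ± 0.32 did not pass (adjusted p = 0.990). Chosen after their values were seen, EXPA15 had an interaction of -1.31 ± 0.34 and EXLA3 of -1.68 ± 0.62, neither past the threshold over all genes, and adjusted over the list alone 1 member passed.

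The dehydrin and LEA list was not called for the interaction (mean 0.07, camera adjusted p = 0.729), nor were the flavonoid, photosynthesis and auxin lists (means -0.01, -0.18 and 0.15, camera adjusted p = 0.895, 0.188 and 0.729). Without hai1-2 stress replicate 2 the photosynthesis list gave an adjusted p of 0.0410, in a range of 0.0410 to 0.623. The root markers' mean interaction was -0.14, with 0.0354, -0.00154 and -0.468 in experiments 1, 2 and 3. AMY1 and DELTA-OAT had interactions of 0.87 ± 0.40 and 0.50 ± 0.17 (adjusted p = 0.990 for both), and adjusted over the list alone 1 of the 2 proline genes passed with a higher response. limma called 0 probe sets with a higher and 1 with a lower response in hai1-2, with 732 at an unadjusted p under 0.05 against 853 by chance. The experiment was not taken out in this fit either, and with it as a block the number was 841.

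**Figure D3:**
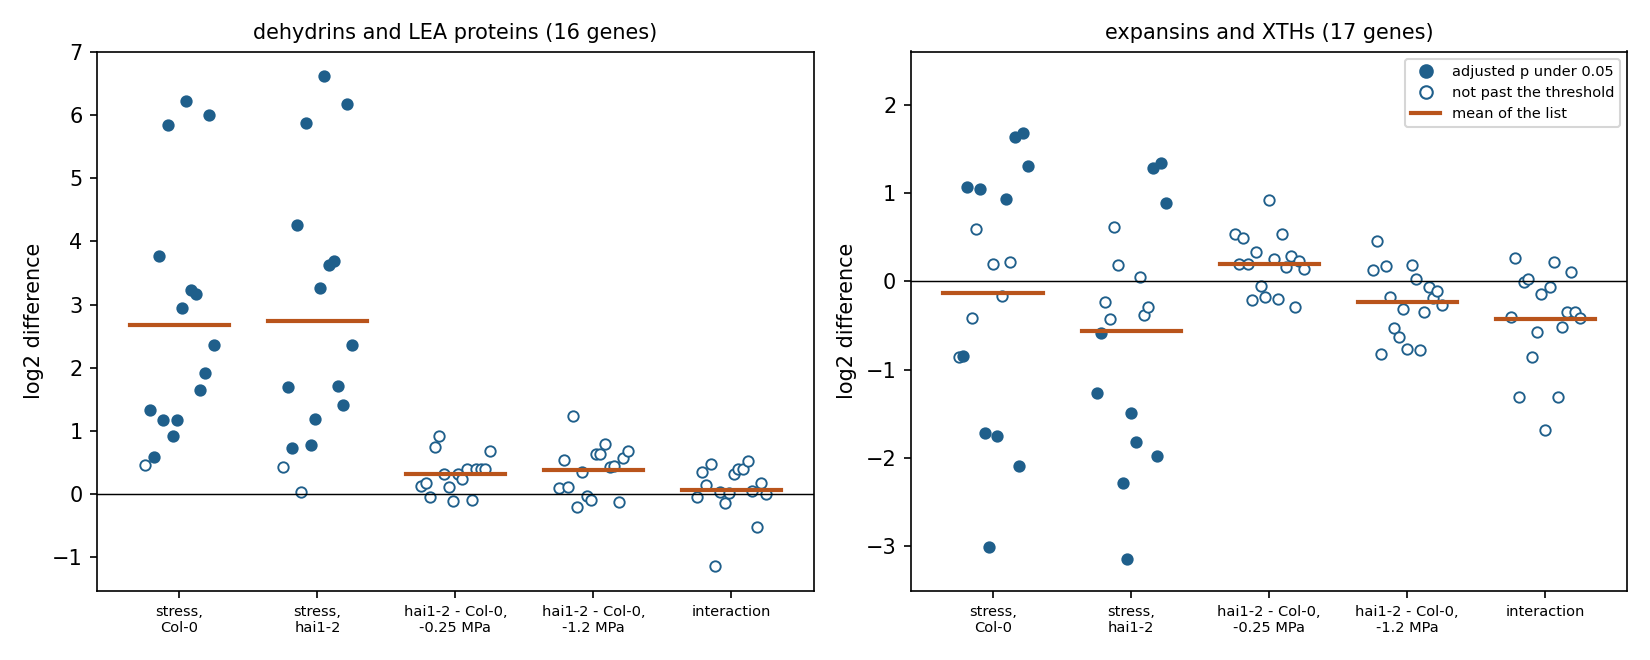
Log2 differences of the 16 dehydrin and LEA genes (left) and the 17 expansins and XTHs (right) in the 5 comparisons, each point 1 gene, filled where its adjusted p was under 0.05, and the bar the list's mean. In the 3 genotype comparisons no point is filled, and the expansin and XTH mean runs from 0.20 on control plates to -0.24 at -1.2 MPa.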

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

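Of the tests in this part, those of a single deviating array, quantile normalization, random lists, the treatment by experiment, the actin ratio, root markers, the GAPDH covariate, the 32 splits that part every pair and the splits with a block were chosen after the results were seen. The items that stood out are 2 responses that differed between the genotypes in the interaction test: that of probe set 247723_at (-2.91) and the mean of the expansin and XTH list (-0.43). The higher level of dehydrin and LEA genes in hai1-2 is weighed beside them.

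Probe set 247723_at was lower in stressed hai1-2, at -3.13 on the log2 scale, in 3 of 3 experiments, and its adjusted p ran from 2.3e-07 to 1.2e-04 over the alternatives. A single deviating array is argued against, since the difference was still -2.98 with the array left out that reduced it most, and normalization between arrays is too, since quantile normalization gave -3.16. RNA quality as the whole cause is argued against too, since the difference was -2.85 (95% interval -3.61 to -2.09) with the GAPDH ratio as a covariate. That holds only as far as a linear fit does, because the ratio did not overlap between the stressed groups. The 10 splits of the 6 stressed arrays are too few for a share under 0.05, with 1 call in the real split and at most 0 in the others, so that 1 split gave as many. In number, this probe set lies between those for AT5G63180 and AT5G54060, and the locus of HAI1 lies between these loci too. It may thus measure HAI1 itself, and its lower signal may then be a mark of the lesion. The annotation names neither its gene nor a probe set for HAI1, so whether the lesion lies in the gene it measures stays open. Until that is known, an effect of the HAI1 genotype on the transcript of another gene remains no more than a hypothesis.

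Dehydrin and LEA genes lay higher in hai1-2 by a mean of 0.38 at -1.2 MPa and 0.31 on control plates, where experiment 2 gave 0.61 and the call was lost with an estimated correlation (adjusted p = 0.0641) or without hai1-2 control replicate 2 (adjusted p = 0.0603, in a range of 7.6e-05 to 0.170). Chance is argued against for this list taken alone, since 1 of 100 drawn splits, the real one, gave a mean over both treatments as large as 0.35. The highest other was 0.30. Among the 32 splits that part every pair, the real one was bound to be the largest, since the list lay higher in hai1-2 in each experiment at both water potentials. Those splits, of which 17 others were among the drawn ones, therefore add no support. The share of 1 in 100 was not adjusted for the 5 lists tested. Normalization and a trend with signal level are argued against as well, with a mean at -1.2 MPa of 0.40 after quantile normalization and a percentile of 100 among 10000 random lists matched on mean log2. A stronger treatment on the plates of hai1-2 would not by itself account for the shift on control plates. It stays open for what was added at -1.2 MPa, which was 0.308, -0.202 and 0.0986 in experiments 1, 2 and 3, and so positive in 2 of 3. With the GAPDH ratio as a covariate, the mean at -1.2 MPa was 0.55, with a 95% interval of 0.13 to 0.97. That interval is wide, and the ratio did not overlap between the stressed groups, so the fit cannot separate RNA quality from genotype. RNA quality therefore stays open as a cause. An effect of the genotype on these transcripts may be the cause, and the causes left open cannot be told apart from it here.

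The expansin and XTH list responded lower in hai1-2, with a mean of -0.43 over 17 genes, though not with an estimated correlation (adjusted p = 0.162) or without hai1-2 control replicate 2 (adjusted p = 0.0854, in a range of 1.7e-04 to 0.329). Chance cannot be excluded, since 12 of 100 drawn splits gave an interaction as large in size as 0.43, up to 0.61, although the other 31 of the 32 splits that part every pair reached at most 0.40. Normalization is argued against by a mean of -0.44 after quantile normalization, and the low actin ratio of Col-0 control replicate 3 by a mean of -0.44 without that array, but RNA quality by the GAPDH ratio stays open, with a mean of -0.51 and a 95% interval of -1.45 to 0.43 with it as a covariate. A smaller share of root tissue in stressed hai1-2 could be a cause in part and stays open, since the 3 root markers cannot decide it. Their mean interaction was -0.14, of which experiment 3 made most (0.0354, -0.00154 and -0.468), while the list was below 0 in 3 of 3 experiments. EXPA7 (-0.49) and EXPA18 (-0.17) are themselves expansins, and PYK10, the only other root marker, stood at 0.22. An effect of the genotype on the genes of the expansin and XTH list is therefore no more than 1 of the open explanations.

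For the counts of called probe sets, the 10 splits of each comparison's 6 arrays are too few for a share under 0.05: the real splits gave 5838 calls in Col-0 and 6421 in hai1-2, with at most 0 in the other splits, so that in each 1 split gave as many. For hai1-2 against Col-0 on control plates the real split gave 0 calls and 10 of 10 splits gave as many, the highest 297. That split set Col-0 control replicates 1 and 3 and hai1-2 control replicate 1 against the other 3 control arrays, which points to a structure of the samples by experiment, as it parts experiments 1 and 2. With the experiment as a block, the real split gave 1 call on control plates and 3 at -1.2 MPa, and the other 3 splits that part all pairs gave 0 in each, while the split of control arrays with 297 calls then gave 1 and 1 further split of stressed arrays gave 2. For the interaction, chance cannot be excluded for the count of 1: 16 of 100 drawn splits gave as many, up to 48, and up to 3 among the other 17 that parted the same pairs.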

How the results depend on the processing

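Pairing within each treatment was chosen after the data were seen, as was the fit with the GAPDH ratio as a covariate, given above and not run for the counts. Of 92 called values of named genes, 82 kept their direction and call in every setting run for them (22 to 24 per value), 0 reversed and 10 lost the call in at least 1 setting. The other 38 values were not called. Most called genes were named for large changes or small adjusted p, so these counts do not describe the called probe sets at large. The causes of the changes below were not tested, except that 1 probe set per gene and the 2-fold minimum leave fewer probe sets, and 6 arrays or 1 array fewer leave fewer samples. Signals near background limit what a change of a weak gene can show. camera has no robust option, so robust moderation was not run for lists, and the interaction could not be fitted to 6 arrays. Calls in Col-0 numbered 1596 higher and 1386 lower with 1 probe set per gene and 1234 and 1258 with the 2-fold minimum, and in hai1-2 1756 and 1507, and 1265 and 1436. With 1 probe set per gene, 0 were lower in the stressed genotype comparison and 0 in the interaction, since the probe set called there has no gene name.

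With the replicate block, 1 probe set was lower in hai1-2 on control plates and 3 at -1.2 MPa, and the uncalled expansin and XTH list in Col-0 turned direction (adjusted p = 0.956); it changed no other count by over 1.5 times and no other list call. The paired differences within each treatment gave 1 higher and 1 lower on control plates, AT2G19970 (adjusted p = 0.0229) and QQS (adjusted p = 0.0195), and 2 higher and 9 lower at -1.2 MPa, among them AMY1 (adjusted p = 0.0370) and GH9B8 (adjusted p = 0.0370). At -1.2 MPa, a pseudocount of 64 gave 1 higher, no trend 1 higher, array weights 3 lower and the 6 arrays alone 2 lower. The Spearman correlation of the responses was 0.756 with no filter.

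Among lists, a pseudocount of 1 turned the LEA interaction (0.880) and quantile normalization the flavonoid interaction (0.922), neither called. Auxin early response in Col-0 lost its call with no filter (0.0819), median centring (0.0503) and an estimated correlation (0.261). In hai1-2 it gained one with array weights (0.0292), 6 arrays (0.0485) and fry (0.0331), and array weights turned its uncalled direction on control plates (0.325) and in the interaction (0.574). The expansin and XTH list in Col-0 turned with 6 arrays (0.953). At -1.2 MPa this list lost its genotype call with no trend (0.0560), an estimated correlation (0.306) and fry (0.372), on control plates with the latter pair (0.163 and 0.404) and in the interaction too (0.162 and 0.329). LEA genes on control plates lost theirs with an estimated correlation (0.0641) and fry (0.170), and photosynthesis in Col-0 with an estimated correlation (0.0570). Photosynthesis on control plates gained a call with the lower 50% removed (0.0395).

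With 1 array left out, the lower calls ran from 0 to 1 on control plates and from 1 to 2 at -1.2 MPa. Adjusted p for auxin early response ran from 0.00866 to 0.0873 in Col-0, 0.0398 to 0.171 in hai1-2, 0.0964 to 0.974 on control plates, 0.353 to 0.984 at -1.2 MPa and 0.172 to 0.983 in the interaction. For expansins and XTHs it ran from 0.582 to 0.997 in Col-0, 0.00108 to 0.314 on control plates, 0.00927 to 0.353 at -1.2 MPa and 0.000168 to 0.0854 in the interaction. For LEA genes on control plates it ran from 7.6e-05 to 0.0603. For flavonoid genes it ran from 0.160 to 0.974 on control plates, 0.232 to 0.984 at -1.2 MPa and 0.594 to 0.983 in the interaction. For photosynthesis it ran from 0.0247 to 0.602 on control plates, 0.199 to 0.984 at -1.2 MPa and 0.0410 to 0.623 in the interaction. SAG101 in Col-0, not called, ran from -0.57 to 0.028.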

Other observations

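All tests in this part were chosen after the annotation or the results were seen. Genes grouped into 38 families by their symbols were tested with camera in the same way, adjusted over the families within a comparison. Genes of the UGT family, which transfer sugars to small molecules such as flavonoids and hormones, leaned upwards at low water potential: of 35, 14 rose and 4 fell in Col-0 (mean 0.62, camera adjusted p = 0.0472, and adjusted p = 0.644 with an estimated correlation). In hai1-2, 17 rose and 5 fell (mean 0.68, camera adjusted p = 0.0329, and adjusted p = 0.329 with an estimated correlation). The flavonoid glucosyltransferase UGT78D2 rose by 2.41 and 2.43, UGT76E12 by 2.82 and 3.17, and UGT85A4 fell, at -2.05 and -1.44, in Col-0 and hai1-2. The 12 IQD genes, of calmodulin-binding proteins, leaned downwards, with 6 that fell and 1 that rose in Col-0 (mean -0.60, camera adjusted p = 0.0472, and adjusted p = 0.488 with an estimated correlation). Both calls in Col-0 were lost after quantile normalization (adjusted p = 0.0538 and 0.0538). In hai1-2 the IQD mean was -0.58 (camera adjusted p = 0.0416, and adjusted p = 0.325 with an estimated correlation).

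Beside the genotype differences in this paragraph, the GAPDH 5' to 3' ratio went from 1.00 to 0.869 in Col-0 and from 0.943 to 1.11 in hai1-2. Beta-tubulin genes, which encode a building block of microtubules, fell in stressed hai1-2 in 4 of 5 cases, with TUB5 at -1.92 and a mean of -0.85 (camera adjusted p = 0.0131, and adjusted p = 0.325 with an estimated correlation). In Col-0, 5 of 5 were negative and 2 fell, with TUB5 at -1.38 and a mean of -0.55 (camera adjusted p = 0.0831). The mean interaction was -0.30 (camera adjusted p = 0.0151, and adjusted p = 0.443 with an estimated correlation and 0.0912 with fry), and no single tubulin gene passed for it. The endoglucanase family GH9 had a negative interaction in 7 of 7 genes, with a mean of -0.56 (camera adjusted p = 0.00291, and adjusted p = 0.144 with an estimated correlation and 0.0832 with fry). At -1.2 MPa it lay lower in hai1-2, with a mean of -0.42 (camera adjusted p = 0.00486, and adjusted p = 0.171 with an estimated correlation and 0.0620 with fry). GH9B8 had a signal of 696 ± 91.8 in stressed Col-0 and 309.7 ± 48.6 in stressed hai1-2 (SD, n = 3), without passing on its own in the genotype comparison (-1.13 ± 0.27, adjusted p = 0.584). The autophagy family ATG had a positive interaction in 8 of 8 genes, with a mean of 0.38 (camera adjusted p = 0.0109, and adjusted p = 0.443 with an estimated correlation and 0.272 with fry), among them ATG8E at 0.91, which did not pass on its own. Directions of these families did not turn under quantile normalization.

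A larger overall response in hai1-2 was tested as a hypothesis for the genotype difference at -1.2 MPa, by the slope of each experiment's hai1-2 minus Col-0 difference on the mean response in the other experiments. The slope was 0.0765, 0.0506 and 0.0662 at -1.2 MPa in experiments 1, 2 and 3, and -0.0128, 0.0551 and -0.00846 on control plates. It was above 0 and above the control slope in 2 of 3 experiments, so a larger response of the mutant may underlie part of the difference over all probe sets, but the hypothesis stays open. The correlations at -1.2 MPa were weak, at 0.189, 0.109 and 0.156 in experiments 1, 2 and 3. Probe set 247723_at, with an interaction of -2.91, rose less in hai1-2 and so went against a larger response.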
